A study of Arabidopsis thaliana with 8 samples.

How the data were processed

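ChIP-seq libraries of Arabidopsis Col-0 leaf and suspension cell culture were used, 1 for each of the 4 antibodies and 2 sample types. Per the labels, the culture was maintained with 1.1 mg/l of a synthetic auxin, subcultured every 7 d, and fixed with 1% paraformaldehyde for 15 min. How leaf tissue was fixed is not stated there. The submitters' processing notes name Bowtie2 and bedtools (no versions) and the TAIR10 genome. Aligner settings, handling of duplicates and of reads that map to several places, and read length are not given in the sources used here.

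The deposited files of the authors hold raw counts, whole numbers of reads for each of 109972 intervals, the same in all 8 files. The intervals are genes, transposable elements and the stretches between them, with 1 line each for plastid and mitochondrion. They comprise 27213 protein-coding genes, 31189 transposable elements of 320 families and 51387 nuclear intergenic intervals. 7169 intervals start before the end of an earlier one, so a read can count more than once. The files give no strand and no position within a gene. H3K4me3 was planned over the first 1 kb of each gene and is given over the whole gene body instead. Gene symbols came from the RefSeq annotation (26907 of 27394 gene IDs matched, 10566 with a symbol), and list members keep the symbols of the lists.

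Reads on nuclear chromosomes numbered 1449274, 2075647, 2160614 and 1811213 in leaf (H3, H3K4me3, H3K27me3, H3K9me2) and 3116646, 3476684, 5649143 and 3261618 in the culture. Counts were scaled to reads per 1000000 nuclear reads after a pseudocount of 1. The change of a feature is the log2 of mark over H3 in the culture minus the same in leaf. Its standard error is the counting error of the 4 counts, and intervals are at the 95% level. Features with fewer than 20 mark reads over both libraries or fewer than 10 reads in either H3 library were left out. A feature rose or fell where the change was at least 2-fold and the interval excluded 0. It was marked where log2 of mark over H3 was at least 1. For a feature with 0 counts on one side, the fold was computed from a floor of 3 counts in that library. That fold leaves out the counting error of the other counts, so it is not a lower limit. With 1 library per group, no test between sample types was run.

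Pericentromeres were fixed as chromosome 1 from 12 to 18 Mb, 2 from 1 to 7, 3 from 11 to 17, 4 from 1 to 6 and 5 from 9 to 15. H3 coverage was computed in 500 kb windows and by arm. The result of each of 14 gene lists (278 genes) is the median change, as a percentile of 10000 random lists matched in 10 bins of read level, with an interval from 200 Poisson resamples of the counts. The lists were floral organ identity and flowering, shoot meristem and homeobox, root and callus regulators, embryo and seed, photosynthesis, cell cycle and DNA replication, DNA methylation and small RNA, imprinted in endosperm, pollen and sperm cell, Polycomb, housekeeping, auxin response and transport, leaf development, and stomatal lineage and trichome. The genes named are, for each mark, the 8 largest rises and 8 largest falls with a symbol, ranked by the interval end nearer 0, and examples from the 2 highest and 2 lowest members of each list. Families named are the 5 highest and 5 lowest medians among those with at least 10 tested elements. These comparisons, lists, naming rules and the pericentromeres were set before the data were examined.

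Chosen after the data were seen were the 100 kb windows (at least 8 genes with at least 5 leaf H3 reads each, as the median log2 ratio of their genes relative to the median gene), the comparison of elements with genes within 100 kb, the split of elements by length, the term H3-dense, and a set of 40 H3-dense arm intervals with leaf H3 over 10 times leaf H3K9me2 (each per 1000000 nuclear reads). An interval is H3-dense where its leaf H3 reads per kb exceed 20 times the gene median. There were 2070 such intervals, with 25 protein-coding genes and 76 elements, holding 26.9% of leaf and 24.9% of culture H3 reads. Gene and element examples named from the 100 kb windows and the element coverage were also chosen after their values were seen.

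Alternatives tried were the mark without H3, a pseudocount of 5, no filter, scaling by the median feature, a 3-fold rule, other windows and regions, features in the middle 90% of H3 counts, and, chosen after the data were seen, library totals without H3-dense intervals, features without a 4-fold difference in H3, the pericentromere without ATREP18 elements, and gene intervals alone. The code was tested on simulated data with known changes. Of simulated log2 changes of 2, it called 96.2% for gene H3K4me3, 86.4% for gene H3K27me3 and 97.2% for element H3K9me2. Of unchanged features it called 2.50%, 2.99% and 2.03%, and the intervals held the true value in 95.6%, 95.9% and 95.4%. The simulated counts were Poisson counts without variation between plants, cultures or immunoprecipitations. These rates therefore check the code and are not error rates of the calls reported here. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.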

Results

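Chromatin of Arabidopsis thaliana Col-0 was profiled by ChIP-seq (sequencing of immunoprecipitated chromatin) in leaves and in a suspension cell culture kept on auxin. 4 antibodies were used, against histone H3 and against H3K4me3, H3K27me3 and H3K9me2. H3K4me3 lies over active genes, H3K27me3 is set by Polycomb over silent developmental genes, and H3K9me2 covers silent transposable elements in heterochromatin. There was 1 library for each antibody and sample type, 8 in all, so there are no replicates. Total read counts in leaf were 1679480 for H3, 2141886 for H3K4me3, 2183580 for H3K27me3 and 1825604 for H3K9me2. In the culture they were 3128553, 3504870, 5672742 and 3289359 in the same order. A median protein-coding gene held 19 leaf and 35 culture H3 reads. Each change below is the log2 of mark over H3 in the culture minus the same in leaf. Its 95% interval covers counting error only, not variation between plants or cultures, and no spike-in was used. A feature rose or fell where the change was at least 2-fold and the interval excluded 0.

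Heterochromatin was compared first, since the series title concerns small-RNA-directed DNA methylation and somaclonal variation, the heritable change that arises in culture. H3K9me2 over the pericentromeres was lower in the culture. Relative to the chromosome arms its log2 enrichment was 2.72 in leaf and 1.7 in the culture, a change of -1.02 (-1.03 to -1.01). All 5 chromosomes had lower values in the culture, from -0.27 on chromosome 3 to -1.64 on chromosome 2. H3K27me3 over the same regions was higher in the culture by 0.59 (0.58 to 0.60), with 1.42 on chromosome 1. Without the elements of 1 family, ATREP18 (below), and the intervals touching them, it was 0.36, and 0.48 on chromosome 1. The H3K4me3 difference was -0.30, and -0.04 once H3-dense intervals, with leaf H3 reads per kb over 20 times the gene median, were left out. Without those intervals the H3K9me2 difference was -0.74 (-0.33, -0.70, -0.98, -0.86 and -1.04 on chromosomes 1 to 5) and the H3K27me3 difference 0.93. Without the division by H3 the H3K9me2 difference was -0.35.

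H3K9me2 over transposable elements was lower in the culture, most of all over LTR retrotransposons. Of 3462 elements with enough reads, 1877 fell and 312 rose, and the median change was -1.24. Without the filter on low counts the median over all 31189 elements was 0.26. The median element held 0 H3K9me2 reads in each library, so that value reflects the pseudocount and library totals and gives no direction. LTR retrotransposons had the lowest medians, -1.88 for Copia (408 elements) and -1.84 for Gypsy (1549 elements). LINE/L1 elements had a median of -1.18 (276 elements), MuDR elements -0.63 (469) and En-Spm elements -0.50 (238). Helitrons, which copy themselves by rolling-circle replication, had a median of 0.41, with 53 of 160 risen and 30 fallen.

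Among families with at least 10 tested elements, ATCOPIA43 had the lowest median, -4.47, and all 11 of its elements fell. ATGP3 had a median of -4.10 (30 of 35 elements fell), ATLINE1_6 of -3.82 (31 of 39), ATCOPIA78 of -3.57 (10 of 11) and HARBINGER of -3.46 (6 of 11). ATCOPIA78 is the heat-activated ONSEN family. The highest medians were 1.34 in ATCOPIA28 (7 of 13 elements rose), 1.32 in HELITRONY2 (11 of 16), 0.97 in ATLINE1A (12 of 30), 0.89 in VANDAL1N1 (4 of 10) and 0.74 in ATHILA4B_LTR (7 of 17). The VANDAL1N1 median was -0.23 without the division by H3. On the arms, elements of over 4000 and up to 8000 bp had a median change of -3.04, with 111 of 162 fallen. In the pericentromeres elements of that length had a median of -2.01, with 454 of 670 fallen. Arm elements of up to 1000 bp had a median of 0.74 (55 elements), but pericentromeric ones of that length -1.04 (138 of 288 fell), and arm elements of over 8000 bp had -1.08 (22 of 42 fell). H3-dense elements were not left out of this split. The 40 H3-dense arm intervals chosen for leaf H3 over 10 times leaf H3K9me2 include 8 elements, all shorter than 1000 bp. That choice favours positive changes, and the median of 0.74 was not recomputed without them.

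By the level that defines a marked element, at least 2-fold mark over H3, 2601 elements were marked in leaf, 1097 in the culture and 817 in both. Of those marked in leaf 1704 fell and 36 rose, or 1022 and 445 when centred on the median element (below). Of the 861 not marked in leaf, 276 rose and 202 of these were marked in the culture. The leaf level that splits the elements also enters the change, so counting error alone adds falls to the marked and rises to the others. The scaling to nuclear reads leaves a shift of -1.24 in the median element. Measured from that median, 1067 elements fell and 988 rose, so 48.1% of the changed elements were higher, against 14.3% before. On that scale the superfamily medians were -0.65 for Copia and -0.60 for Gypsy, but 0.06 for LINE/L1, 0.60 for MuDR, 0.73 for En-Spm and 1.65 for Helitrons, so LINE/L1, MuDR and En-Spm elements change direction with the scaling. The 5 families with the lowest medians stayed below 0 there, from -3.23 to -2.22.

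**Figure D1:**
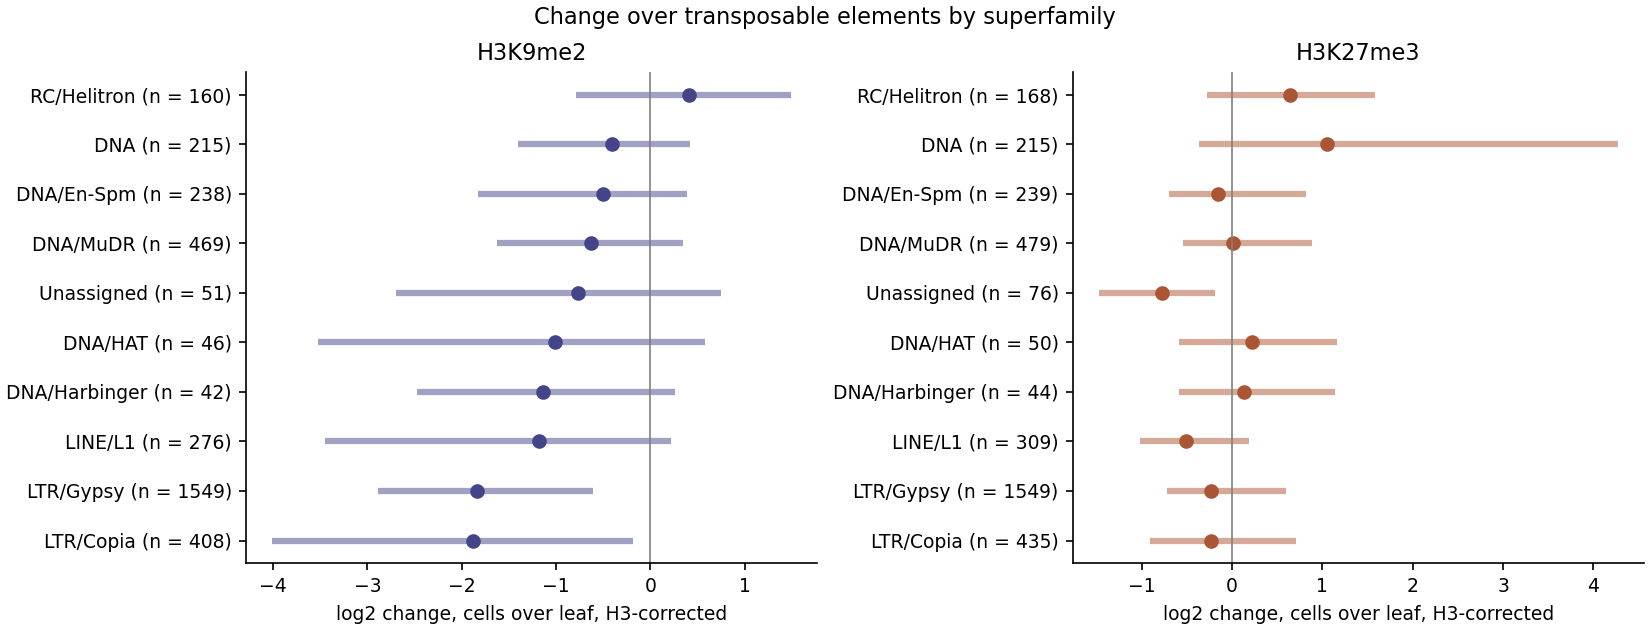
Change of H3K9me2 (left) and H3K27me3 (right) over transposable elements by superfamily, as log2 of the H3-corrected culture level over the leaf level. Points are medians over the n elements given on each axis, and bars span the quartiles (not an error). Copia and Gypsy elements have the lowest H3K9me2 medians, -1.88 and -1.84. On a scale centred on the median element the LINE/L1, Harbinger, HAT, MuDR, En-Spm, DNA and unassigned medians of H3K9me2 turn positive.

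H3K27me3 was not higher over the elements that lost H3K9me2. Over the 1863 elements in which H3K9me2 fell, the median H3K27me3 change was -0.40 (178 rose, 305 fell). Over the other 1559 elements it was 0.41 (493 rose, 121 fell). All 100 tested elements of the ATREP18 family (below) rose in H3K27me3, and this contrast was not recomputed without them. Without the division by H3, which both marks share, the medians were -0.14 and 0.71. Across elements, which are not independent replicates, Spearman's rho between the 2 changes was 0.40. Counts simulated without any change gave 0.58, because the H3 libraries are shared, and the covariance was 1.05 against 0.123 in those counts.

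The ATREP18 family gained H3K27me3 in all 100 tested elements, with a median change of 4.38. The family's share of nuclear reads went from 0.153% in leaf to 6.36% in the culture for H3K27me3, from 0.203% to 0.466% for H3, from 0.131% to 0.273% for H3K4me3 and from 1.09% to 3.16% for H3K9me2. HELITRONY2 had a median of 1.72 (9 of 15 rose), ATHILA8A of 1.46 (18 of 30), ATHILA4B_LTR of 1.46 (9 of 16) and VANDAL2N1 of 1.39 (12 of 19). The lowest medians were -0.92 in SADHU, -0.89 in ATGP3, -0.85 in ATLANTYS3, -0.83 in ATGP2N and -0.82 in ATLINE1_5. Without H3 these medians were -1.37, -0.13, -0.39, -0.08 and -0.33. Over all 3575 tested elements 696 rose and 466 fell, 59.9% higher, and 70.1% were higher when centred on the median element.

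H3K27me3 over genes rose most at AGL31 (AT5G65050, chromosome 5, 25982254 to 25986326), by 6.51 (5.38 to 7.63). Its neighbour MAF3 (AT5G65060) rose by 4.99 (3.94 to 6.04) and MAF1 (AT1G77080) by 4.67 (3.78 to 5.56). All 3 are relatives of the floral repressor FLC. TCP2 (AT4G18390), a TCP factor of leaf shape, rose by 4.89 (3.79 to 5.99) and the homeobox gene BLH2 (AT4G36870) by 2.95 (2.29 to 3.61). NRPB6B, an RNA polymerase subunit gene, rose by 4.56, the lipid transfer gene LTP by 3.25, and the zinc-finger homeodomain gene HB33 by 3.18.

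The largest fall was at ASL1 (AT5G66870, chromosome 5, 26705862 to 26708676), a LOB-domain gene, with a change of -6.85 (-8.08 to -5.63). PR-1-LIKE changed by -6.15 (-7.83 to -4.48), the channel gene KCO3 by -5.80 and EDA31 by -5.66. GIK and AHL20, both AT-hook genes, changed by -5.79 and -5.47. WRKY62 changed by -5.39 and RSH2 by -5.60. RSH2 lies 69 bp from AT1G12960. These named rises and falls exceeded the shift in the median gene given next.

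**Figure D2:**
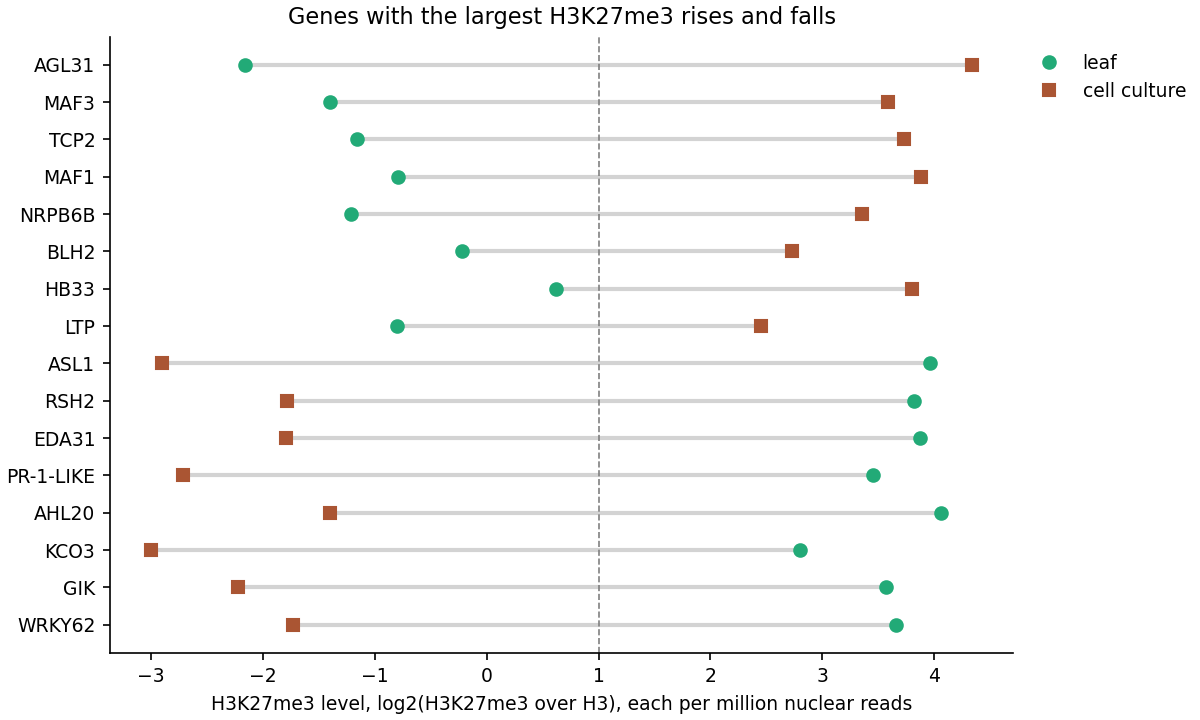
H3K27me3 level, as log2 of mark over H3 with each per 1000000 nuclear reads, in leaf (circles) and culture (squares) for the 8 genes with the largest rise and the 8 with the largest fall. The dashed line is the level of 1 that defines a marked gene, and counting intervals of the changes stand in the text. AGL31 went from -2.16 in leaf to 4.34 in the culture, and ASL1 from 3.96 to -2.90.

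Of 19845 protein-coding genes tested for H3K27me3, 5308 fell and 547 rose, and the median change was -0.57. Measured from that median 2344 fell and 1709 rose, so 42.2% of the changed genes were higher, against 9.34% before. In leaf 3846 genes were marked, in the culture 2371, and 2139 in both. Of the genes marked in leaf 1882 fell and 116 rose, and 1327 and 410 when centred. The median change was -0.98 over genes marked in leaf and -0.52 over the others. The leaf level that splits them also enters the change, so counting error alone lowers the former median and raises the latter.

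Each gene list was set against 10000 random lists matched on read level, as a percentile of the median change. These percentiles do not depend on the shift of -0.57. For H3K27me3, floral organ identity and flowering genes stood highest, at 1.19 above the median gene (percentile 100.0). Of 17 measured members 2 rose and 15 did neither, and 11 rose when centred. AG, which specifies stamens and carpels, rose by 1.13 and its relative SHP1 by 1.09. AG lies 183 bp from a neighbour and SHP1 overlaps GAUT15. LFY had a change of -0.43 (-1.20 to 0.33) and AGL24 of -0.80 (-1.60 to 0.00). Of these genes 17 were marked in leaf and 16 in the culture. Without H3 the list median was 0.07 (percentile 96.8), inside the central 95% of random lists, and SHP1 did not pass.

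Leaf development genes stood 1.01 above the median gene for H3K27me3 (percentile 99.8), with 5 risen, 2 fallen and 6 neither. YAB5 rose by 2.43. Without H3 the list median was -0.91 (percentile 19.0), so the direction of the list rests on the division, and YAB5 did not pass. The abaxial regulator KAN2 changed by -3.0 and the adaxial regulator AS2 by -2.19. Auxin response and transport genes stood lowest, at -0.66 relative to the median gene (percentile 1.3), with 9 fallen, none risen and 7 neither. GH3.2, an auxin-conjugating enzyme gene, changed by -4.06 (-4.82 to -3.29). PIN3 had a change of 0.45 (-0.49 to 1.39).

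Among root and callus regulators 6 fell, none rose and 8 did neither (median -1.05, percentile 6.4). WOX11, a regulator of callus and adventitious roots, changed by -4.13 and PLT3 by -3.67, the latter 168 bp from RBK1. BBM had a change of 0.41 (-0.20 to 1.03). Of shoot meristem and homeobox genes 4 fell, 1 rose and 6 did neither (median -0.42, percentile 66.5). KNAT6 changed by -4.14 and KNAT2 by -3.47, WOX2 rose by 1.34, and STM had a change of 0.78 (0.17 to 1.38). The rise of WOX2 was not called without H3. Of embryo and seed genes 6 fell and 10 did neither (median -0.61, percentile 40.0), among them AGL15 at -3.44, a MADS gene of embryo tissue.

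The remaining lists had H3K27me3 medians inside the central 95% of random lists. They were 0.14 for stomatal lineage and trichome genes (percentile 95.8), where GL3 changed by -2.02 and ATML1 rose by 1.01. Housekeeping genes had -0.20 (94.8), photosynthesis genes -0.30 (73.3), DNA methylation and small RNA genes -0.64 (70.2) and Polycomb genes -0.67 (40.4). Pollen and sperm cell genes had -0.75 (32.1), cell cycle and DNA replication genes -0.67 (24.3) and genes imprinted in endosperm -0.86 (13.2).

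In the culture H3K4me3 was lower over photosynthesis genes and higher over cell cycle genes. Of 25 measured photosynthesis genes 13 fell, 1 rose and 11 did neither, with a median of -1.12 (percentile 0.0). LHCB1.2, a light-harvesting gene 69 bp from CARB, changed by -3.48 (-4.59 to -2.36) and PSBO2, of the oxygen-evolving complex, by -2.76. PSAD1 rose by 1.26, though not without H3, and lies 170 bp from a neighbour. Of 38 cell cycle and DNA replication genes 20 rose, none fell and 18 did neither, with a median of 1.07 (percentile 100.0). The cyclin gene CYCA1;1 rose by 3.21 (2.03 to 4.38) and the kinase gene AUR1 by 2.67 (1.32 to 4.03). MAP65-3 had -0.60 (-1.37 to 0.17) and HINKEL -0.61 (-1.37 to 0.15). Centred on the median gene, 15 cell cycle genes rose and none fell.

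Leaf development genes had a median H3K4me3 change of -0.63 (percentile 0.3), with 3 fallen, none risen and 10 neither, among them YAB3 at -2.20 and TCP10 at -1.77. Shoot meristem genes had -0.62 (percentile 2.1), with 3 risen, 1 fallen and 7 neither. KNAT1 rose by 1.56 and the boundary gene CUC2 by 1.59, WOX2 changed by -1.94, and the median was -0.16 (percentile 54.9) without H3. Embryo and seed genes had -0.50 (percentile 2.7), with 6 fallen, 2 risen and 8 neither. The storage protein gene SESA3 changed by -2.94 and DOG1 by -2.43, while AGL15 rose by 1.5 and LEC2 by 1.27. The rise of KNAT1 was not called without H3, nor that of LEC2, which also ended under other scalings and a pseudocount of 5. Root and callus regulators had -0.09 (21.5), with WOX11 up by 2.38 and PLT3 by 2.07, and SHR at -1.89. Auxin genes had 0.07 (49.1), with 4 risen and 5 fallen. IAA29 rose by 2.72 and the auxin synthesis gene YUC8 changed by -2.33.

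The H3K4me3 medians of the other lists were -0.48 for stomatal lineage and trichome (percentile 5.8), -0.29 for pollen and sperm cell (21.6), -0.08 for imprinted (22.9) and 0.03 for Polycomb genes (31.3). Floral genes had 0.12 (57.5), housekeeping genes 0.17 (60.8) and DNA methylation and small RNA genes 0.24 (74.8). SEP3, a floral MADS gene, changed by -2.75. Of the Polycomb genes none of 13 rose or fell.

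**Figure D3:**
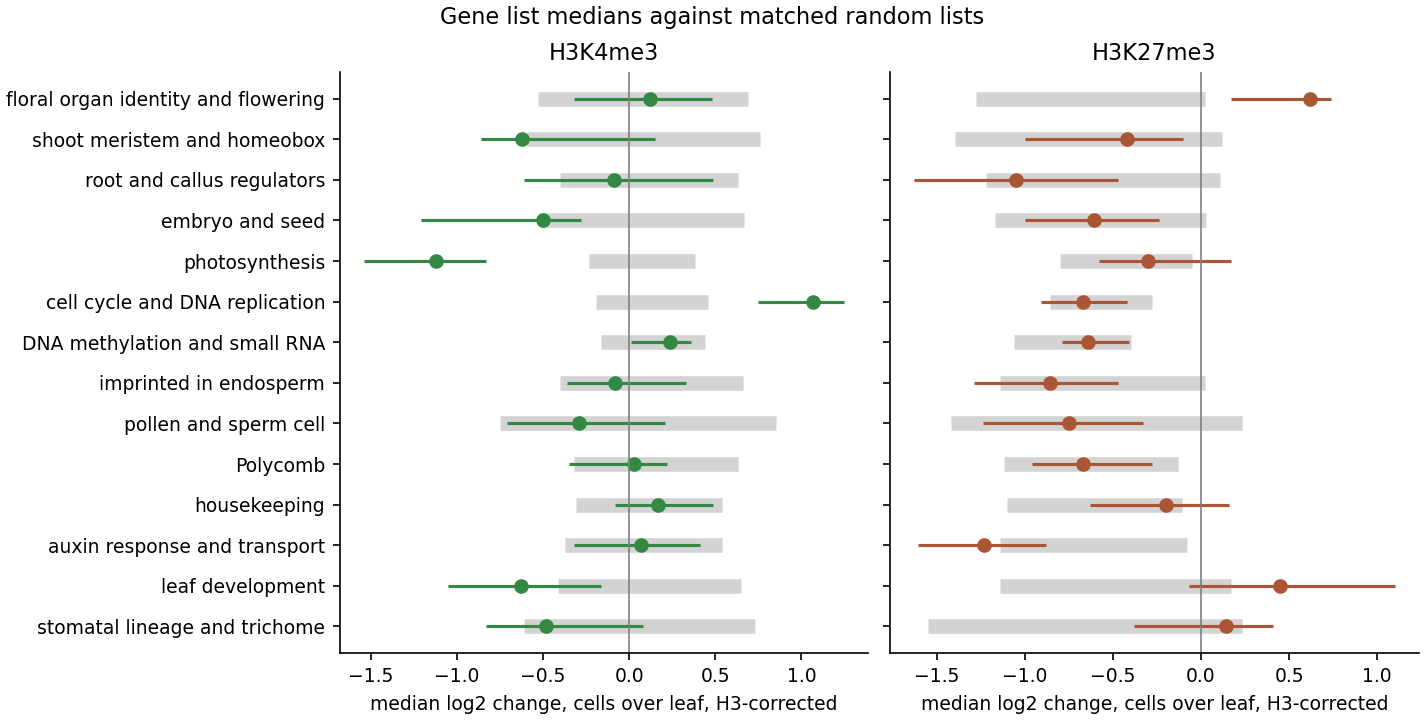
Median log2 change, culture over leaf and H3-corrected, of the 14 gene lists for H3K4me3 (left) and H3K27me3 (right). Points are medians, thin lines their 95% counting intervals and grey bars the central 95% of 10000 matched random lists. For H3K4me3, photosynthesis genes lie at -1.12 and cell cycle genes at 1.07, on either side of their random lists.

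By the ranking over all genes, H3K4me3 rose most at EXPA4 (AT2G39700, chromosome 2, 16543832 to 16545584), a cell wall expansin, by 5.48 (4.07 to 6.90). PAP25, an acid phosphatase, rose by 3.84, FD3, a ferredoxin, by 3.75, the meiotic recombinase gene DMC1 by 3.53, CYP708A3 by 3.48 and PS2 by 3.45. NF-YC8 had 1 leaf and 60 culture reads, a change of 4.43 (2.14 to 6.72). eIF6B, 73 bp from DAR2, had 0 leaf reads and a change of 5.34 (2.29 to 8.39), or 13.0-fold from the floor of 3 counts. H3 itself changed by -1.81 at EXPA4 and -1.59 at FD3.

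H3K4me3 fell at PMI1 (AT1G42550), needed for chloroplast movement, with a change of -3.49 (-4.29 to -2.70), and at the vacuolar malate carrier gene TDT, with -3.19. The glycosyltransferase genes UGT74D1 and UGT73B2 changed by -3.66 and -3.43, CYP71B7 by -3.54 and EXO70H5, of the exocyst, by -3.67. ELP had 61 leaf reads and 1 in the culture, a change of -4.70 (-7.01 to -2.40). PMI1 lies 183 bp and CYP71B7 148 bp from a neighbour. Of 20473 genes tested 2606 rose and 1751 fell (59.8% higher), with a median change of 0.11. Centred on that median 2106 rose and 2121 fell (49.8% higher). In all 4673 genes were marked in leaf, 5977 in the culture and 3474 in both. Without the division by H3, 3041 fell and 2114 rose.

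Loss of H3K27me3 and gain of H3K4me3 met in 655 of the 19258 genes tested for both, against 621 for independent lists. The reverse, H3K27me3 risen and H3K4me3 fallen, held in 64 genes against 42.9. Of the 655 genes 333 were marked by H3K27me3 in leaf, and of the 64 genes 46 were marked in the culture. WOX11, PLT3 and AGL15 were among the former by the values above. The H3 libraries enter both marks, and without them the counts were 600 against 808 and 64 against 101. Centred on the median gene these counts were 360 against 221 and 168 against 169. Both marks fell in 661 genes against 458 and rose in 87 against 58.0, or 1480 against 1126 and 321 against 72.2 without H3, and 360 against 245 and 218 against 152 when centred. With the shared H3 libraries, counts simulated without any change gave 51.85 genes with both marks fallen and 42 with both risen. They gave 0.15 genes with H3K27me3 fallen and H3K4me3 risen, and 0.1 for the reverse. Across genes, which are not independent replicates, Spearman's rho was 0.12, against 0.50 in simulated counts without change.

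H3K9me2 rose at 1311 genes and fell at 655 of the 6124 tested outside H3-dense intervals, in a mark that most genes lack. ER (AT2G26330, chromosome 2, 11208183 to 11213971), the ERECTA receptor kinase, went from 3 to 373 reads, a change of 6.24 (4.73 to 7.74). AO1, an aldehyde oxidase gene 26 bp from its neighbour, rose by 5.31 (3.96 to 6.65). IDD12 and the carboxypeptidase-like gene scpl44 had 0 leaf reads and changes of 6.37 (3.43 to 9.3) and 6.26 (3.36 to 9.15). From the floor of 3 counts they were 26.6-fold and 24.8-fold higher. ADR1-L3, an immune receptor relative, changed by -4.21 (-5.15 to -3.27) and GNC, a GATA factor of greening, by -4.57 (-6.48 to -2.66) with 2 culture reads. AGL92 changed by -4.24, with an H3 change of 2.16. NCED2, of abscisic acid synthesis, changed by -3.76, CYSC1 by -3.79 (-5.48 to -2.09) with 3 culture reads, FMO GS-OX2 by -3.31, ATSYP24 by -2.93 and DMT2, a DNA methyltransferase gene 159 bp from a neighbour, by -2.74.

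4 more genes were among the 8 largest positive H3K9me2 changes, TPPI at 5.98, MEE27 at 5.88, ACS2 at 5.77 and PUX3 at 5.00. Their leaf H3 coverage was over 20 times that of the median gene, and H3 changed there by -2.74, -2.78, -2.82 and -2.31. All 4 belong to a set of 40 H3-dense arm intervals, chosen after the data were seen for leaf H3 over 10 times leaf H3K9me2, a choice that in itself favours positive changes. The median H3 change over the set was -2.78 (quartiles -2.83 and -2.7), and the set held 0.381% of leaf and 3.17% of culture H3K9me2 reads. Culture H3K9me2 relative to leaf H3 had quartiles of -1.6 and -1.48 over the set. From the medians of the set the H3K9me2 change is 5.77, close to the values of TPPI, MEE27 and ACS2. These values thus follow a profile common to the set and are not particular to these genes. Whether the reads of the set stem from these genes could not be checked without sequences. Over all 6147 genes tested 1326 rose and 656 fell (66.9% higher), with a median of 0.34. Centred on it 885 rose and 1034 fell (46.1% higher). Of the 1317 risen genes that were not marked in leaf, 169 were marked in the culture. Outside H3-dense intervals 156 genes gained marking, 89 of them on the arms, and 107 lost it, 53 on the arms.

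The cell cycle genes had an H3K9me2 median of -0.32 (percentile 3.9), with 4 risen, 3 fallen and 8 neither. It was 0.15 (25.2) without H3, 0.25 (34.5) with no filter and 0.01 with totals without H3-dense intervals, so its direction is not settled. HINKEL rose by 2.52 (0.38 to 4.66) from 1 leaf read, and CYCA3;2 changed by -2.15. MCM3 had 0 leaf reads and a change of 3.94 (1.02 to 6.85), or 4.88-fold from the floor of 3 counts. DNA methylation and small RNA genes had 0.32 (54.0), with 7 of 29 risen and 1 fallen. Among them SUVH5, a histone methyltransferase gene for this mark, rose by 4.83 (3.28 to 6.38) from 3 leaf reads. AGO6 rose by 3.84 (1.72 to 5.96) from 1 leaf read, and AGO4, 49 bp from ENODL20, changed by -1.87. The culture level was 1.15 at SUVH5, but -1.53 at AGO6, -2.05 at HINKEL and -1.78 at MCM3. The last 3 thus stayed below the level of 1 that defines a marked gene.

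Floral genes had an H3K9me2 median of 1.12 (87.0), with 4 of 10 risen. STK, 63 bp from a neighbour, rose by 2.06. AP3, with 0 leaf reads, had a change of 3.68 (0.68 to 6.68), or 3.96-fold from the floor of 3 counts. Imprinted genes had 0.84 (86.8), stomatal and trichome genes 0.85 (81.9), leaf development genes 0.36 (64.9), auxin genes 0.60 (63.3) and root and callus regulators 0.81 (46.7). PLT1 and TTG1 had 0 leaf reads and changes of 4.21 (1.31 to 7.12) and 3.46 (0.55 to 6.36). From the floor of 3 counts they were 5.95-fold and 3.5-fold higher. Culture levels were 1.08 at STK, but -0.73 at AP3, -1.36 at PLT1 and -1.87 at TTG1, below the level of 1 that defines a marked gene. With a pseudocount of 5 the calls of HINKEL and TTG1 ended. With genes of 0 counts set to the floor of 3 counts the medians were the same. The shoot meristem, embryo and seed, photosynthesis, pollen, Polycomb and housekeeping lists had fewer than 5 members with enough reads. In all, 7 of the 36 medians of lists and marks lay outside the central 95% of random lists.

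H3 coverage was uneven between the tissues. Of 240 windows of 500 kb, 12 were at least 2-fold higher in the culture and 17 at least 2-fold lower, with log2 ratios from -2.36 to 2.42. The highest was chromosome 2 from 1.0 to 1.5 Mb, at 2.42 (2.37 to 2.47), and the next chromosome 3 from 11 to 11.5 Mb, at 1.92 (1.87 to 1.97). In the latter window 1 transposable element, AT3TE45800, held 9637 of 30986 culture H3 reads and 85 of 3815 leaf H3 reads. The lowest was chromosome 2 from 9.5 to 10.0 Mb, at -2.36 (-2.39 to -2.33). Its leaf H3 reads numbered 28076, against 4464 and 4145 in the adjoining windows, and its culture reads 11742 against 5827 and 7842. 3 H3-dense intervals of a set described above held 24277 of these leaf and 7524 of these culture reads. They adjoin one another and 1 of them spans 1 bp, so the same read can count in all 3. With protein-coding gene intervals alone only 3 windows were lower. By arm, the right arm of chromosome 2 had -1.06 (-1.07 to -1.05), or -0.60 in genes that are not H3-dense, and its left arm 0.60 (0.59 to 0.61), or 0.72 in genes.

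Windows of 100 kb, chosen after the data were seen and based on gene medians, narrowed some of these regions. Of 1032 windows, 57 were at least 2-fold higher than the median gene and 10 at least 2-fold lower. Chromosome 2 from 1.0 to 1.1 Mb stood at 3.40, with all 29 genes above 2-fold. Chromosome 1 from 23.3 to 23.4 Mb also stood at 3.40, with 16 of 22 genes above 2-fold. Chromosome 3 from 7.9 to 8.0 Mb stood at 2.19 and holds TIC, a gene of the circadian clock, with 97 leaf and 5845 culture H3 reads. Chromosome 3 from 10.9 to 11 Mb stood at 2.45 and holds AAR3, with 8 and 1095 reads. At the left end of chromosome 4, the window from 0.0 to 0.1 Mb stood at -1.51 and that from 0.3 to 0.4 Mb at -1.82.

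**Figure D4:**
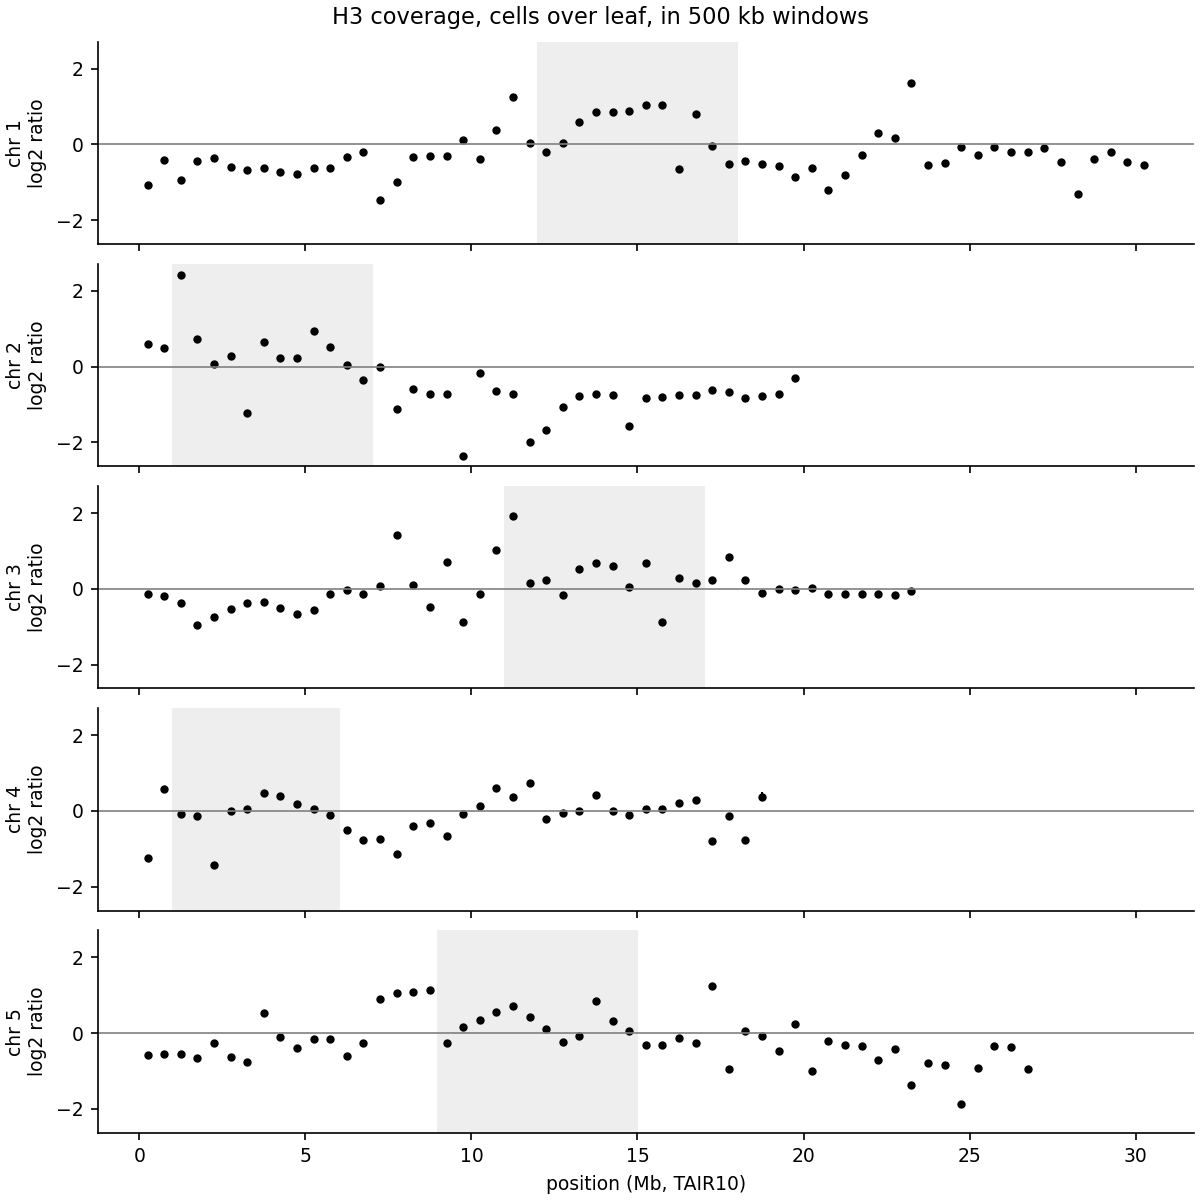
H3 coverage in the culture over leaf, as the log2 ratio of reads per 1000000 nuclear reads in 500 kb windows, along the 5 chromosomes (position in Mb). Points are windows, vertical lines are 95% counting intervals (mostly smaller than the points) and grey bands are the pericentromeres. Values run from -2.36 on chromosome 2 at 9.5 to 10.0 Mb to 2.42 on the same chromosome at 1.0 to 1.5 Mb. In the lowest window 3 H3-dense intervals hold 24277 of 28076 leaf reads.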

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

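The tests of the 3 patterns weighed here, windows with more H3, LTR elements with less H3K9me2 and the ATREP18 family, were all chosen after the results were seen. For replication timing and for a weaker immunoprecipitation, other tests were run earlier and set aside, since the choice of windows, differences between single elements or an assumed background decided their outcome.

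3 signals lay outside the comparisons or stood in few intervals. Plastid reads made up 12.2% of the leaf H3 library, and 2.49%, 0.757% and 0.0686% of leaf H3K4me3, H3K27me3 and H3K9me2. In the culture they made up 0.0331% of H3, 0.422% of H3K4me3, 0.169% of H3K27me3 and 0.131% of H3K9me2. A set of 40 H3-dense intervals on the arms (13 genes, 8 elements and 19 intergenic), chosen after the data were seen for leaf H3 over 10 times leaf H3K9me2, held 9.12% of nuclear leaf H3 reads and 1.34% of culture H3 reads, with 5.38%, 1.55% and 0.381% in leaf H3K4me3, H3K27me3 and H3K9me2. In the culture the shares of these marks were 1.16%, 0.593% and 3.17%. The origin of these reads is not known, since no sequences were at hand. One intergenic interval on chromosome 3, from 14199916 to 14205307, held 5.97% of culture and 3.01% of leaf H3K9me2 reads, with 2.64% and 1.7% of the H3 reads.

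57 windows of 100 kb stood at least 2-fold above the median gene in H3 reads, culture over leaf. The log2 ratio of the median gene itself was -0.29. Noise or bias of the single H3 library is argued against by the other culture libraries, whose lowest median over these windows was 1.21 (1.21 for H3K4me3, 1.35 for H3K27me3, 1.45 for H3K9me2 and 1.39 for H3). Replication timing in dividing cells would keep coverage within 2-fold of the median gene. It is argued against as the whole cause by the 3 mark libraries, which did not select the windows: the middle of their log2 ratios had a median of 1.34 (1.15 to 1.52) and exceeded 1 in 44 of 57 windows. That interval takes the windows as independent, which adjoining windows are not, so it may be too narrow. A gain of chromosome segments in the culture would place the windows side by side. Of the windows 40 adjoined another, against 0 to 13 in the central 95% of 1000 random placements. Any cause that acts over whole regions would do so too, and random placement removes all likeness between neighbours. Adjoining windows therefore do not set gained segments apart from such causes. Gained DNA segments remain a candidate explanation, a hypothesis that DNA sequencing of the same cells would test.

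H3K9me2 over LTR elements was lower in the culture. A weaker immunoprecipitation that dilutes all elements alike would keep LTR families in the order of their leaf levels. Among 400 pairs of families whose order was certain in leaf, 152 (38.0%) were certainly reversed in the culture. The pair of ATGP1 (2.36 in leaf, 2.00 in the culture) and ATHILA2 (2.54 and -0.08) is an example. These reversals argue against such dilution as the whole cause, within 2 limits. Certain order rests on 1000 resamples of the elements within each family, in 1 library per group, and leaves out variation between libraries. The pairs come from only 35 families, so the same family recurs in many of them and they are not independent. Scaling to the library totals is argued against as the whole cause by the median of 1957 LTR elements, which was -0.61 at its highest among 4 scalings, by the median element (-1.84 with nuclear totals, -1.51 without H3-dense intervals, -2.18 by the median gene). Without the division by H3 the median was -1.42, which argues against the division as the cause. A share of the fall due to any of these, and a difference between the tissues, stay open.

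H3K27me3 was higher over ATREP18 elements, which held 0.153% of nuclear leaf H3K27me3 reads and 6.36% of those of the culture. Every culture library did hold more reads over the family. Its share went from 0.203% to 0.466% for H3, from 0.131% to 0.273% for H3K4me3 and from 1.09% to 3.16% for H3K9me2. Division by H3 removes a gain common to all libraries, and the median H3K27me3 change after it was 4.38. The H3-corrected changes of H3K9me2 and H3K4me3 were 0.42 and -0.08. A common gain is thus argued against only as the whole cause. Reads of one locus shared out over near-identical copies stay open, since the files do not say which reads map once. The median change was 4.32 on chromosome 1 (82 elements, 15.09 to 15.41 Mb) and 4.72 on chromosome 4 (14 elements, 3.2 to 3.26 Mb), and such sharing would give both. A difference between leaf and culture chromatin stays open as well, untested.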

How the results depend on the processing

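Library totals without H3-dense intervals, features without a 4-fold H3 difference, the pericentromere without H3-dense intervals or without ATREP18 elements and windows of gene intervals alone were alternatives chosen after the data were seen. Of 91 recomputed main values, 59 stayed within 1.5 times the main count or within its interval, and for the 32 others the cause was not tested unless stated. A count that stayed can still change its meaning. Without H3 the overlaps of 600 and 64 genes stayed, but lay below the 808 and 101 of independent lists instead of above them. Gene lists were compared by how many medians lay outside the random lists, 5 without H3 against 7, not by which lists. Without the division by H3, elements with risen H3K9me2 numbered 522, genes with fallen H3K4me3 3041, the H3K27me3 medians of elements were -0.14 with and 0.71 without H3K9me2 loss, and the pericentromere change was -0.35. With a pseudocount of 5 the median without loss was 0.34. With no filter more elements were tested, and 3311 fell and 867 rose in H3K9me2, with H3K27me3 medians of -0.43 and 0.20. The median H3K9me2 change then turned to 0.26, a value set by the pseudocount and library totals, since the median element held 0 H3K9me2 reads. Scaling by the median feature, which removes the shift, gave 1067 fallen and 988 risen elements, 2344 fallen and 1709 risen genes in H3K27me3, overlaps of 360 and 168, and a median of 0.30 without loss. A 3-fold rule, stricter by construction, gave 192 risen elements, 2667 fallen and 279 risen genes in H3K27me3, and 744 fallen and 1125 risen in H3K4me3. Totals without H3-dense intervals gave a median of 0.34 without loss. The pericentromere change was -1.08 as a median over intervals and -0.74 without H3-dense intervals, and that of H3K27me3 was 0.36 without ATREP18 elements and intervals touching them. Windows of 1 Mb, which are fewer, gave 4 higher and 7 lower. Intervals in the middle 90% of leaf H3 reads gave 4 lower windows, scaling by the median window 19 higher and 11 lower, and gene intervals alone 3 lower.

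Of 216 recomputed list medians 20 changed sign, 8 of them without the division by H3, and 23 percentiles crossed 50, 16 of them there, with the cause not tested. There shoot meristem H3K4me3 went to -0.16, leaf development H3K27me3 to -0.91, and floral H3K27me3 to 0.07 (percentile 96.8), while the photosynthesis H3K27me3 percentile went from 73.3 to 99.3. Of 1395 values of named genes 1288 kept their call, 76 lost it and 27 gained it. Of the losses 28 came under the 3-fold rule, 18 without the division by H3 and 14 with scaling by the median feature. 4 turned without the division by H3, SHP2 H3K4me3 to -0.16, ATML1 H3K4me3 to 0.50, GEX2 H3K27me3 to 0.08 and CYCA2;2 H3K9me2 to 0.15, and the cause was not tested. The first 1 kb of genes and the gene body with 1 kb upstream were not run, since the files hold whole intervals without strand. For H3K9me2, 3462 of 31189 elements and 6147 of 27213 genes had enough reads.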

Other observations

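No test was run on the observations below, and all were chosen after the values were seen, except the family and gene lists, which followed the naming rules.

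H3K4me3 over transposable elements rose at 512 and fell at 359 of 3383 tested elements. The highest family medians were 1.52 in ATENSPM5 (20 of 28 elements rose), 1.10 in ATLINE1_6 (22 of 40), 1.00 in ARNOLD2 (6 of 11), 0.94 in VANDAL6 (9 of 23) and 0.89 in TAG2 (4 of 11). ATLINE1_6 was also among the 5 families with the lowest H3K9me2 medians, at -3.82. The lowest H3K4me3 medians were -0.98 in ATGP2, -0.95 in ATGP10, -0.91 in ATLINE1_2, -0.87 in ATDNA12T3_2 and -0.82 in ATGP2N. Without H3 these were 0.26, -0.21, -0.16, -0.42 and -0.14. Elements that lost H3K9me2 had a median H3K4me3 change of 0.08 (352 of 1830 rose), and the others -0.15 (136 of 1420 rose). Without H3 the medians were 0.43 (453 of 1586) and 0.27 (365 of 1664), so the direction of the others turns.

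Genes of DNA methylation differed one by one. In H3K4me3 AGO6 rose by 1.78, though not without the division by H3, and AGO4 by 1.57, both Argonautes of small-RNA-directed methylation, while DRM1, a methyltransferase gene, changed by -1.39 and CLSY2 by -1.26. AGO4 lies 49 bp from ENODL20. In H3K27me3 DRM1 changed by -3.92 (-4.68 to -3.16) and AGO5 by -2.66, and the demethylase gene DML3 rose by 1.77 (1.08 to 2.46). FWA and SDC, both known to be silenced by DNA methylation, rose in H3K4me3 by 1.36 and 1.99, at 114 bp and 29 bp from a neighbour. SDC also rose in H3K9me2, by 1.99 (0.01 to 3.97) from 2 leaf reads, to a culture level of -0.55, which is not marked. Among imprinted genes HDG9 and HDG3 changed by -1.26 and -1.19 in H3K4me3 (HDG9 not without H3), and HDG8 by -2.69 in H3K27me3. PKR2 rose by 2.58 in H3K9me2 (1.04 to 4.12) from 3 leaf reads, to a culture level of -1.65, which is not marked.

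Some transposable elements had more H3 reads in the culture than the genes within 100 kb of them. Of 1593 elements with at least 20 leaf H3 reads, 136 exceeded those genes at least 2-fold. Some did so mainly because the genes stood low, and how many was not counted. AT2TE15490, on chromosome 2 from 3547954 to 3552491, had a log2 H3 ratio of 0.69 against -2.80 in the genes. AT3TE45800, an ATCOPIA5 element on chromosome 3 from 11016111 to 11020804, had 85 leaf and 9637 culture H3 reads, 42.5-fold above them. AT2TE42810, a VANDAL21 element on chromosome 2 from 10001480 to 10009658, had 60 and 2735 reads, 36.8-fold above them. 6 of 18 VANDAL21 elements exceeded 2-fold, as did 10 of 18 ATGP2 and 12 of 23 ATGP2N elements.

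On chromosome 2 from 3.4 to 3.5 Mb the H3 ratio of genes was -2.53, while that of H3K27me3 was 0.48, that of H3K4me3 -0.30 and that of H3K9me2 -1.01. Mitochondrial reads made up 1.54% of the leaf and 0.348% of the culture H3 library. On chromosome 4 from 2.2 to 2.3 Mb the ratio was -1.63 in H3 and -2.44 in H3K4me3. The first 10.5 kb of chromosome 2 held 2.93% of leaf and 4.39% of culture H3 reads, and 3.87% and 7.48% of H3K9me2 reads.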
